A study of Mus musculus with 2 samples.

How the data were processed

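Messenger RNA was measured in 2 pooled samples of mouse oocytes at metaphase II, 1 from mothers kept in enriched-environment cages (slimming) and 1 from mothers kept in normal cages (control). Per the labels' protocols, 9 oocytes per group were lysed in 1 tube, their mRNA was primed through an oligo(dT) stretch of 24 bases, a tail was added to the cDNA for second-strand priming, and the product was amplified for 18 and then 14 PCR cycles before sequencing on a SOLiD 4 instrument. Genome build mm9 is named in the submitters' processing notes. The aligner, the counting program, the treatment of reads with several matches and the use of strand are not given in the sources used here. The labels' protocols name no molecular identifiers, so copies made by PCR cannot be separated from independent molecules.

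The deposited table holds 36227 Ensembl genes, each with its chromosome and no coordinates. The authors deposited raw read counts per gene, with the slimming library first and the control library second per the file headers. Counts were given for 18017 genes, and for the other 18210 genes both entries were left blank as missing, which was read as no count in either library. The deposited log2 ratio compares the counts of the 2 libraries, and a second deposited log2 ratio was scaled by the authors. Recomputing that ratio from the counts showed that it equals scaling by the total count with 0 replaced by 0.5, with a largest gap of 7.1e-15. The deposited score of each gene, a z-score made by the authors, compares the 2 libraries per the file headers. The deposited p-value and the q-values derived from it compare the reads of the 2 libraries, with no replicate behind them, and the authors marked genes at a p-value of 0.001.

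Gene symbols were matched by Ensembl identifier to GENCODE vM21, an annotation of a later build (GRCm38) that was used for names, for transcript length and GC content and for which genes overlap. Of the genes with counts, 16913 matched a symbol and 1104 did not; the unmatched genes held 1.66% of the slimming counts and 1.56% of the control counts. No symbol was shared by more than 1 gene. An annotation of mm9 was not used here.

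The total count was 20947962 in the slimming library and 20242289 in the control library, and a count of 0 allows up to 3 counts, or 0.143 and 0.148 CPM (counts scaled to the library total). Libraries were scaled with TMM factors of 1.01 (slimming) and 0.989 (control) from edgeR 4.0.16 in R 4.3.3. The log2 ratio of slimming over control was computed after adding 0.5 to each count. Its 95% interval came from the exact Clopper-Pearson interval of the slimming counts among the counts of both libraries. Intervals and floors cover counting error only. CPM values use the total counts. Genes with at least 10 CPM in at least 1 library were called expressed, which left 5714 genes. Tables were handled in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

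With 1 library per group no test of the groups was possible and no p-value was computed. Genes were counted by size, at least 2-fold higher or lower in the slimming library. For each of 25 gene lists, the median log2 ratio of its expressed members minus the median of the expressed genes was taken as its shift, with a 95% order-statistic interval. Its percentile was read among 10000 random lists of the same size, drawn from expressed genes matched in 20 bins of mean expression. Lists below percentile 2.5 or above 97.5 were called apart. Marker lists for 6 other cell types were summed in each library, with the exact interval of the slimming share of the counts. The lists, the thresholds and the rule for naming genes were fixed before the data were examined.

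Genes were named by the following rule. The 12 largest and the 12 smallest log2 ratios were taken among expressed genes whose counting interval excluded a ratio of 1, passing over predicted and clone names, of which there were 2 on the higher side and 1 on the lower side. In addition, 10 oocyte genes were always named, together with the 5 most abundant genes of each library. From each list apart the 4 members with the largest ratio in the list's direction were named, from the other lists the 2 members with the largest absolute ratio, and from the marker lists the 3 most abundant members. Any other gene named was chosen after its value was seen, and 1 gene that the rule names is not reported here.

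The 2-fold rule and the intervals were tested on simulated counts with the depth of these libraries. Of 200 genes given a 4-fold change among 5475 genes, 100% were found at least 2-fold apart, 0 unchanged genes were, and 95.0% of the intervals held the true ratio. For the lists, 200 random lists of 20 genes were drawn from the observed log2 ratios of the 2 libraries. Of these, 4.5% lay outside the limits without a shift and 98.5% lay above the upper limit when a log2 shift of 0.4 was added. The simulated counts held counting error only, and the random lists came from the same ratios as their comparison lists. These shares therefore say nothing about variation between pools or in PCR, or about lists whose members vary together. At this depth a 4-fold change was all but sure to pass the 2-fold rule, and changes near 2-fold were not simulated. Alternatives covered scaling by total count or by DESeq2 1.42.0 size factors, the authors' scaled ratio, an added value of 5, minima of 1 and 50 CPM and none, other fold thresholds, the mean in place of the median, and coarser matching. Matching on transcript length or GC content, and removing a trend on both, were added after the data were seen.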

Results

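The transcriptome of mature mouse oocytes was compared between mothers that had been through a slimming regime and control mothers. Female ICR mice, an outbred strain, were obese by 12 weeks of age in standard cages and then lived for 4 weeks in enriched-environment cages or in normal cages. At 16 weeks, ovulated oocytes arrested at metaphase II were taken from 3 mice per group, 3 per mouse, and the 9 oocytes of a group were amplified and sequenced as 1 library. The slimming library held 20947962 counts over 15831 genes and the control library 20242289 counts over 16466 genes. The comparison asks how the mothers' way of life relates to the mRNA of their oocytes. Because each group was 1 library, no difference given here has a replicate check, and each describes these 2 libraries and not the conditions.

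The most abundant mRNAs were those of the oocyte itself. Gdf9, an oocyte growth factor that acts on the surrounding granulosa cells, led both libraries with 44674 CPM (counts scaled to the library total) in the slimming and 45613 CPM in the control library, a log2 ratio of -0.06. H1foo, the oocyte linker histone, followed at a log2 ratio of -0.12, and Tcl1 and Bpgm were next at 0.04 and -0.21. Next came Pttg1 (securin) in the slimming library, at a log2 ratio of 0.16, and Lsm14b, an RNA-binding protein of stored maternal mRNA, in the control library. Lsm14b differed most among these genes, with 6243 CPM in the slimming and 13429 CPM in the control library, 2.20-fold lower (log2 -1.14, 95% counting interval -1.15 to -1.13). The top 5 genes held 13.5% of the slimming and 13.9% of the control counts.

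The 3 zona pellucida genes, which encode the egg coat, were each higher in the slimming library. Zp3 (ENSMUSG00000004948, chromosome 5), was 2.05-fold higher (log2 1.03, interval 1.01 to 1.05). Zp1 (ENSMUSG00000024734, chromosome 19) was 1.92-fold and Zp2 (ENSMUSG00000030911, chromosome 7) 1.75-fold higher, at log2 ratios of 0.94 and 0.81. Other oocyte genes were close to equal. Bmp15, the partner growth factor of Gdf9, had a log2 ratio of 0.25, and the maintenance DNA methyltransferase Dnmt1 had 0.16. Mos, the kinase that holds the metaphase II arrest, had -0.05, the maternal-effect genes Ooep and Dppa3 had 0.05 and 0.05, and Nlrp5 had -0.03, a sign that turned with scaling by total count. Across the list of oocyte-specific and maternal-effect genes, 18 of 32 expressed members lay above and 14 below the median of the expressed genes, 1 was at least 2-fold higher (Zp3) and 0 were lower. The list's shift was 0.03, at percentile 87.1 of the random lists.

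Among the largest differences, Nupr1 (ENSMUSG00000030717, chromosome 7), a stress-induced nuclear protein, was 10.5-fold lower in the slimming library, with 3.25 CPM against 33.7 CPM (log2 -3.40, interval -3.79 to -3.05). The zinc finger homeobox gene Zfhx4 and Abcb11, the bile salt export pump, were 9.70-fold and 8.94-fold lower. Tspo, a protein of the outer mitochondrial membrane, was 7.10-fold lower, Slc35d2, a nucleotide sugar transporter, 6.72-fold, and Pigh, which acts in GPI anchor synthesis, 5.52-fold. Inpp4a, a phosphoinositide phosphatase, and Lgals3, a galectin that macrophages also make, were 5.16-fold and 5.14-fold lower. Fam83g, the most abundant of this group at 43.6 CPM against 177 CPM, was 4.15-fold lower, and Rrp8, Cyp4v3 and Rmdn3 were 3.95-fold, 3.92-fold and 3.85-fold lower. Immune cell markers were lower in the slimming library, the direction of Lgals3, with a sum of 27.6 CPM against 51.5 CPM. Of that sum, H2-Aa alone held 17.9 CPM in the slimming and 27.2 CPM in the control library.

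On the other side, Reg3g (ENSMUSG00000030017, chromosome 6), an antimicrobial lectin, was 7.91-fold higher in the slimming library, with 14.6 CPM against 1.78 CPM (log2 2.98, interval 2.5 to 3.54). Fstl1, a secreted follistatin-like protein, was 7.35-fold higher. Mertk, a receptor tyrosine kinase that takes part in the uptake of dying cells, was 6.25-fold higher at 88.5 CPM against 13.8 CPM. Map4k4, Slc29a2 (a nucleoside transporter) and Ercc5 (a nuclease of excision repair) were 6.07-fold, 6.0-fold and 5.63-fold higher. Sec14l2 was 5.29-fold and Acacb, the acetyl-CoA carboxylase that limits mitochondrial fatty acid uptake, 5.09-fold higher. Epdr1, Oas1f, Chst5 and Mkks were between 4.65-fold and 4.33-fold higher. Of the 24 genes with the largest differences, Abcb11, Cyp4v3, Fam83g, Mkks, Pigh, Rmdn3 and Rrp8 share exon sequence with another annotated gene, so with strand not stated their counts are uncertain, and Oas1f belongs to a family of close copies.

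**Figure D1:**
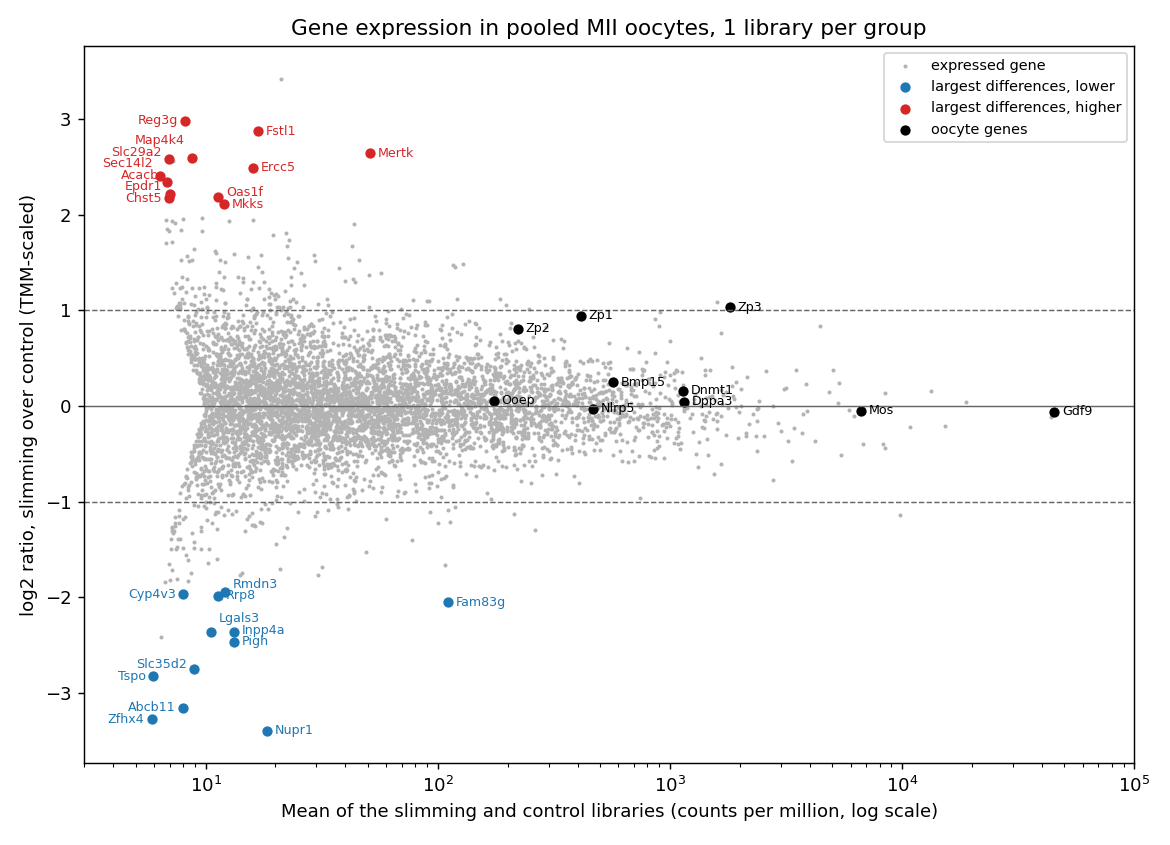
Each point is an expressed gene, placed by the mean of the slimming and control libraries in CPM (log scale) and by its log2 ratio of slimming over control; dashed lines mark 2-fold. Genes named by size are red (higher) and blue (lower) and the oocyte genes black; 156 genes lie at or above the upper line and 111 at or below the lower one.

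Of 5714 expressed genes, 156 (2.73%) were at least 2-fold higher and 111 (1.94%) at least 2-fold lower in the slimming library, and 78 and 57 of them had a counting interval wholly beyond 2-fold. The remaining 5447 genes (95.3%) were less than 2-fold apart. Across expressed genes, which are not independent replicates, Pearson's r of log2 expression was 0.970 and Spearman's rho 0.958. Over genes called expressed or not, the spread of the log2 ratio was above that of counting alone at each level of mean expression. It was 0.83 against 0.24 between 1 and 10 CPM, 0.45 against 0.11 between 10 and 30 CPM and 0.28 against 0.02 between 300 and 1000 CPM. Several genes with the largest differences, such as Zfhx4, Abcb11, Reg3g and Acacb, had a mean of the 2 libraries under 10 CPM. Their counting intervals do not cover that wider spread. In the authors' deposited table, 5485 genes were marked at a p-value of 0.001, 2961 higher and 2524 lower in the slimming library, of which 3361 were under 2-fold apart on the authors' scaled ratio; that p-value compares the reads of 2 libraries.

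Nuclear genes of complexes I, III and IV of the respiratory chain and of ATP synthase were higher in the slimming library as a group. Of 42 expressed nuclear-encoded members of the oxidative phosphorylation list, 32 lay above and 10 below the median of the expressed genes. Ndufa2 (ENSMUSG00000014294, chromosome 18), a subunit of complex I, was 2.26-fold higher (log2 1.18, interval 0.96 to 1.41), and Cox6a1 (ENSMUSG00000041697, chromosome 5), a subunit of cytochrome c oxidase, was 2.02-fold higher at 334 CPM against 161 CPM. Ndufb9 and Uqcr10 were 1.94-fold and 1.88-fold higher. The ATP synthase subunit Atp5k went the other way, at a log2 ratio of -1.11; it is named because it was the 1 member at least 2-fold lower, after its value was seen. The list's shift was 0.45 (95% interval 0.18 to 0.64), a median 1.36-fold higher relative to the expressed genes, above each of the 10000 random lists (percentile 100). Its members have short transcripts, with a median of 813 nucleotides, and the log2 ratio was higher for short transcripts in general, with a median of 0.18 in the shortest of 5 equal groups of genes and -0.09 in the longest. With that length trend removed, the shift was 0.22 (0.0039 to 0.41).

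Genes of oxidative stress defence were also higher, with 15 of 19 expressed members above the median of the expressed genes and 0 at least 2-fold apart. Gstm5, a glutathione transferase, had 1207 CPM in the slimming and 599 CPM in the control library (1.97-fold, log2 0.98, interval 0.95 to 1.01). On the authors' scaled ratio Gstm5 was just past 2-fold higher (log2 1.01). The mitochondrial peroxiredoxin Prdx5, the glutathione transferase Gstp1 and the mitochondrial thioredoxin Txn2 were 1.72-fold, 1.71-fold and 1.51-fold higher. The list's shift was 0.39 (0.06 to 0.53), at percentile 99.99. With the length trend removed the shift was 0.25 and its interval, -0.08 to 0.54, included 0.

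**Figure D2:**
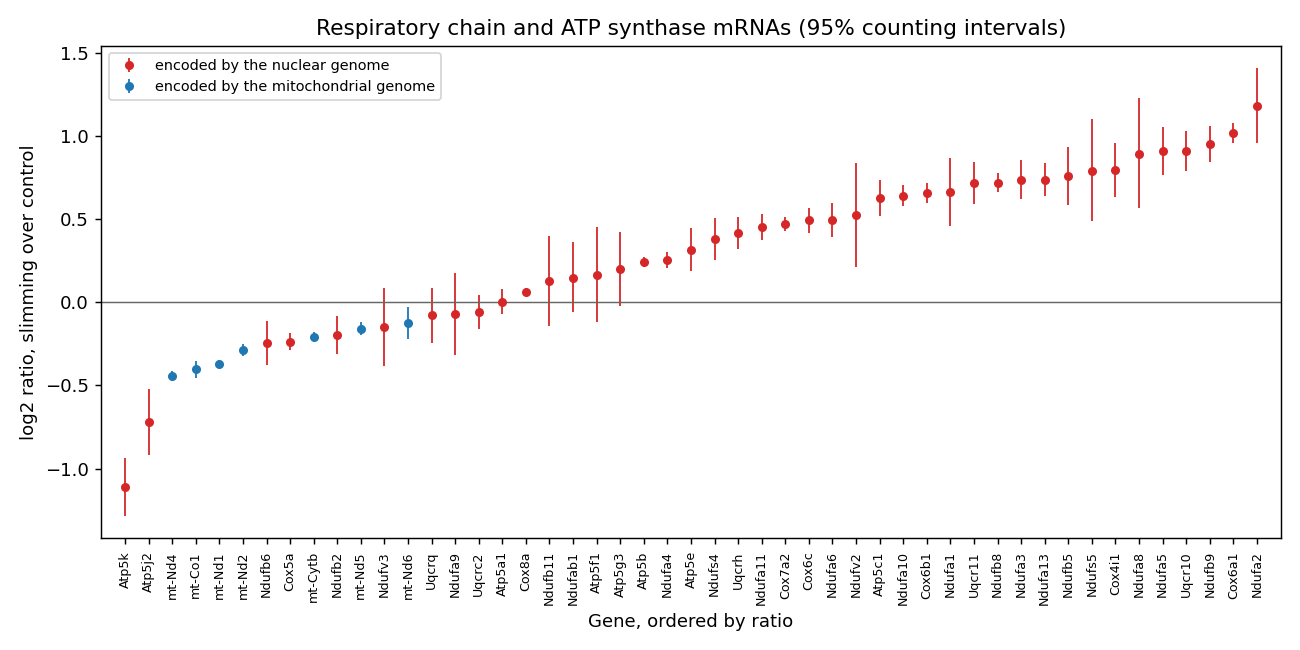
Log2 ratio of slimming over control, with 95% counting intervals, for 42 nuclear-encoded genes of the oxidative phosphorylation list (red) and 7 protein-coding genes of the mitochondrial genome (blue), a set added after the data were seen, ordered by ratio. The red points reach from Atp5k at -1.11 to Ndufa2 at 1.18, and the blue points lie between -0.44 (mt-Nd4) and -0.12 (mt-Nd6).

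**Figure D3:**
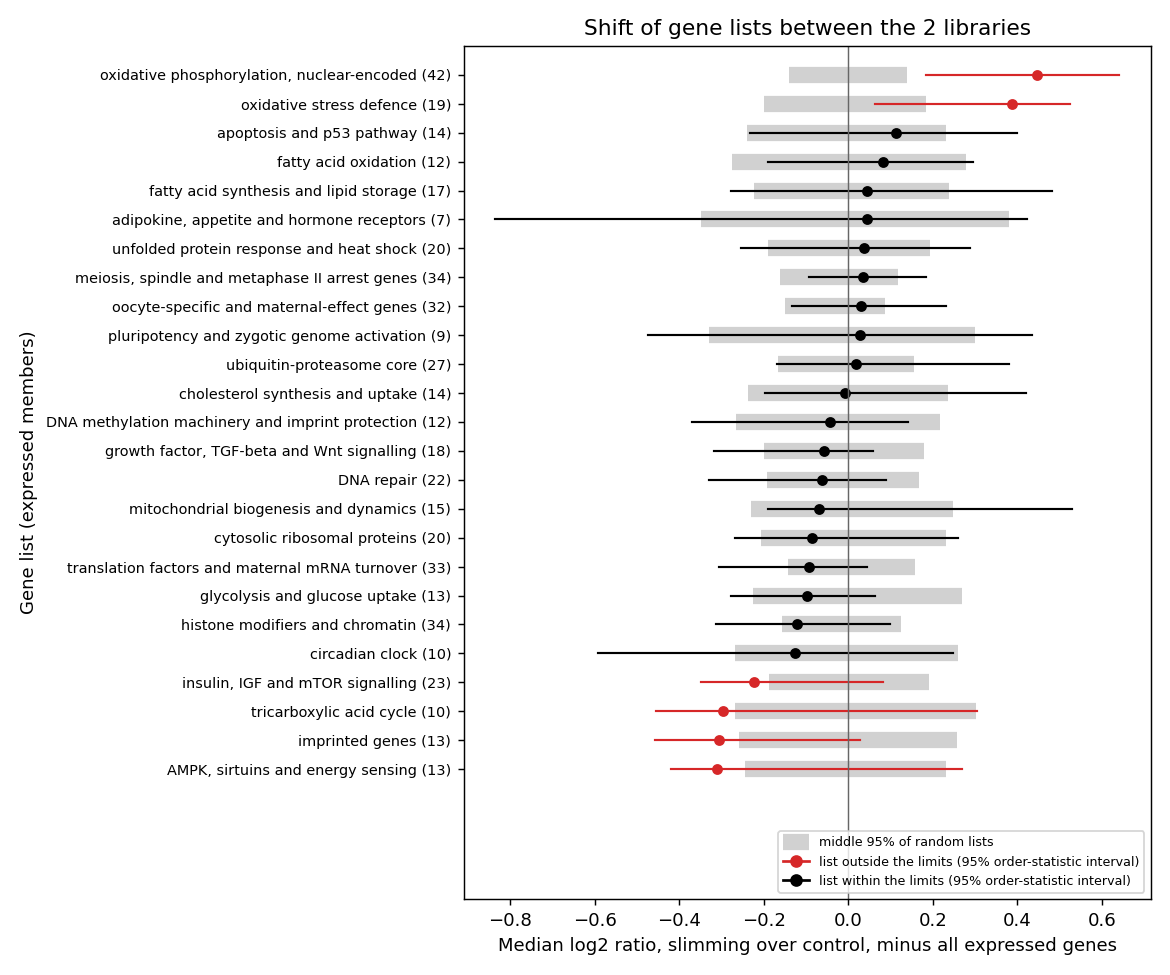
Median log2 ratio of slimming over control for the expressed members of 25 gene lists, minus that of the expressed genes, with 95% order-statistic intervals (lines) over the middle 95% of random lists matched on expression (grey bars); the number of members is in brackets. The 6 lists outside the limits are red, with oxidative phosphorylation at 0.45 and oxidative stress defence at 0.39 on the higher side.

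Lists of energy sensing and growth signalling genes had lower medians in the slimming library. In the AMPK and sirtuin list, 9 of 13 expressed members lay below the median of the expressed genes. Arnt, the partner of hypoxia-inducible factor, was 1.60-fold lower, the AMPK subunit Prkab2 1.36-fold, the AMPK-activating kinase Stk11 1.32-fold and Txnip, an inhibitor of thioredoxin, 1.27-fold, and the list's shift was -0.31 (percentile 0.68). In the insulin, IGF and mTOR list, 16 of 23 members lay below. Ptpn1, a phosphatase that switches off the insulin receptor, was 3.13-fold lower (log2 -1.65, interval -1.99 to -1.33), Gsk3a and Gsk3b were 1.80-fold and 1.76-fold lower and Pik3ca 1.53-fold lower, and the list's shift was -0.22 (percentile 1.03). Among tricarboxylic acid cycle genes 8 of 10 members lay below, with Sdhc 1.39-fold, Sucla2 1.36-fold, Ogdh 1.33-fold and Dlst 1.28-fold lower and a shift of -0.30 (percentile 1.58). Among imprinted genes 10 of 13 lay below, with Phlda2 1.60-fold, Grb10 1.36-fold, Igf2 1.36-fold and Gnas 1.31-fold lower and a shift of -0.31 (percentile 1.14). In that list 1 member was at least 2-fold higher and 0 were at least 2-fold lower. Lists of independently drawn genes would lie outside the limits in 1.25 of 25 cases, where 6 were found. Members of a list can vary together and some genes are in more than 1 list, so the 1.25 does not measure chance here. The intervals of these 4 shifts included 0, and each list moved inside the limits under at least 1 other setting: AMPK to percentile 5.70 and imprinted genes to 6.63 with length and GC trends removed, the insulin list to 3.87 against length-matched lists and the tricarboxylic acid cycle to 8.44 with the mean.

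The other 19 lists lay within the limits at the main settings, and 4 of them (glycolysis, DNA repair, translation factors and ribosomal proteins) moved outside on the lower side under at least 1 other setting. In energy metabolism, Pdha1, a subunit of pyruvate dehydrogenase, was 2.32-fold lower and Pkm 1.59-fold higher in the glycolysis list, whose shift was -0.10 (percentile 19.5). The fatty acid oxidation list, with Hsd17b4 at log2 0.60 and Ppard at -0.41, had a shift of 0.08 (percentile 72.8). Acacb stood against Elovl1, 1.99-fold lower, in the fatty acid synthesis list (shift 0.04, percentile 65.7). Insig1, a brake on sterol synthesis, was 2.15-fold lower and Nr1h2, a sterol-sensing receptor, 1.77-fold higher in the cholesterol list (shift -0.01, percentile 48.5). In the list of mitochondrial biogenesis and dynamics, Timm44 and Fis1 were 1.95-fold and 1.67-fold higher, with a shift of -0.07 (percentile 27.9). The glucocorticoid receptor Nr3c1 was 1.77-fold lower and the prolactin receptor Prlr 1.35-fold higher among 7 expressed hormone and adipokine receptors (shift 0.04, percentile 59.4).

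In cell cycle and chromatin lists, the kinase Mapk3 was 2.14-fold and the phosphatase Cdc25b 1.82-fold higher among meiosis genes, whose shift was 0.03 (percentile 78.1). Uhrf1, which recruits Dnmt1 to DNA, was 1.81-fold lower and Dnmt3l, a cofactor of methylation in the growing oocyte, 1.54-fold higher in the DNA methylation list (shift -0.04, percentile 47.5). The histone methyltransferase Kmt2d and the demethylase Kdm1a were 2.13-fold and 1.89-fold higher in the chromatin list, in which 20 of 34 members lay below the median of the expressed genes (shift -0.12, percentile 7.18). Ung, a uracil DNA glycosylase, was 2.47-fold lower at 154 CPM against 371 CPM in the DNA repair list (shift -0.06, percentile 29.8). Bid and Apaf1 were 1.44-fold and 1.38-fold higher among apoptosis and p53 genes (shift 0.11, percentile 85.1). Nfil3 and Timeless were 1.61-fold and 1.49-fold lower among clock genes (shift -0.13, percentile 18.9), Smad4 was 1.75-fold lower and Egfr 1.57-fold higher among growth factor genes (shift -0.06, percentile 33.3), and Nfyb was 1.60-fold lower and Pou5f1 1.43-fold higher among pluripotency genes (shift 0.03, percentile 62.6).

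In protein synthesis and turnover, the initiation factor Eif3d was 3.47-fold higher and the helicase Eif4a1 2.33-fold lower, in a list of translation and mRNA turnover with a shift of -0.09 (percentile 10.8). Rplp1 was 1.43-fold higher and Rps2 1.51-fold lower among ribosomal proteins, a family with many pseudogene copies (shift -0.09, percentile 20.2). With length and GC trends removed, the ribosomal protein list had a shift of -0.32 at percentile 0.15. The proteasome ATPase Psmc3 was 3.54-fold and the polyubiquitin gene Ubb 2.64-fold lower in the ubiquitin-proteasome list (shift 0.02, percentile 59.9). Ppp1r15a, which reverses the stress arrest of translation, was 2.64-fold higher and Sel1l 1.84-fold lower in the unfolded protein response list (shift 0.04, percentile 67.3).

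Marker transcripts of other cells were counted in both libraries and were unequal for some cell types. Immune markers summed to 579 counts in the slimming and 1043 in the control library, a slimming share of 35.7% (exact 95% interval 33.4 to 38.1) where equal levels would give 51.4%. Of 11 immune markers with at least 10 counts, 10 were lower in the slimming library and 7 at least 2-fold lower. The most abundant were H2-Aa at 17.9 CPM against 27.2 CPM, Cd68 at 3.77 against 5.09 CPM and Laptm5 at 4.11 against 3.71 CPM. H2-Aa held 374 of the 579 slimming and 550 of the 1043 control counts. The immune sum thus rests largely on 1 gene and does not by itself measure the RNA of immune cells. Fcer1g and Tyrobp, partners of immune receptors named after their values were seen, had 0 counts in the slimming and 62 and 57 counts in the control library. Against a floor of 3 counts per library they were 21.9-fold and 20.1-fold lower, and their counting intervals ended at log2 -4.11 and -3.98. Cumulus and granulosa markers summed to 545 and 547 CPM, mostly from Serpine2 (491 against 475 CPM), with Cyp19a1 and Nr5a2 next. Yet 7 of the 13 members with at least 10 counts were at least 2-fold lower and 0 at least 2-fold higher. Inhibin alpha (Inha), also named after its value was seen, had 0 against 63 counts.

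Oviduct markers summed to 247 CPM in each library, nearly all from Cdh1 at 240 and 233 CPM. Of the 6 members with at least 10 counts, 3 were at least 2-fold lower and 0 at least 2-fold higher. Sums carried by 1 gene, as here, for sperm (Odf2) and for cumulus and granulosa cells (Serpine2), do not measure the RNA of those cells. Tppp3 was 2.38-fold lower, and Dnah5 had a log2 ratio of 0.69 with an interval (-0.26 to 1.73) that included 0. Markers of sperm and spermatids summed to 561 and 650 CPM, nearly all from Odf2 (538 and 624 CPM) with Prm2 and Oaz3 next. Red blood cell markers stood at 1.24 and 0.840 CPM, from Epb42 and a single count of Slc4a1. Markers of the 2-cell embryo stood at 13.8 and 12.1 CPM, nearly all from Arg2 and Sp110, with 1 count of Pramef25 in each library and, named after its value was seen, 1 count of Zscan4f in the slimming library.

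**Figure D4:**
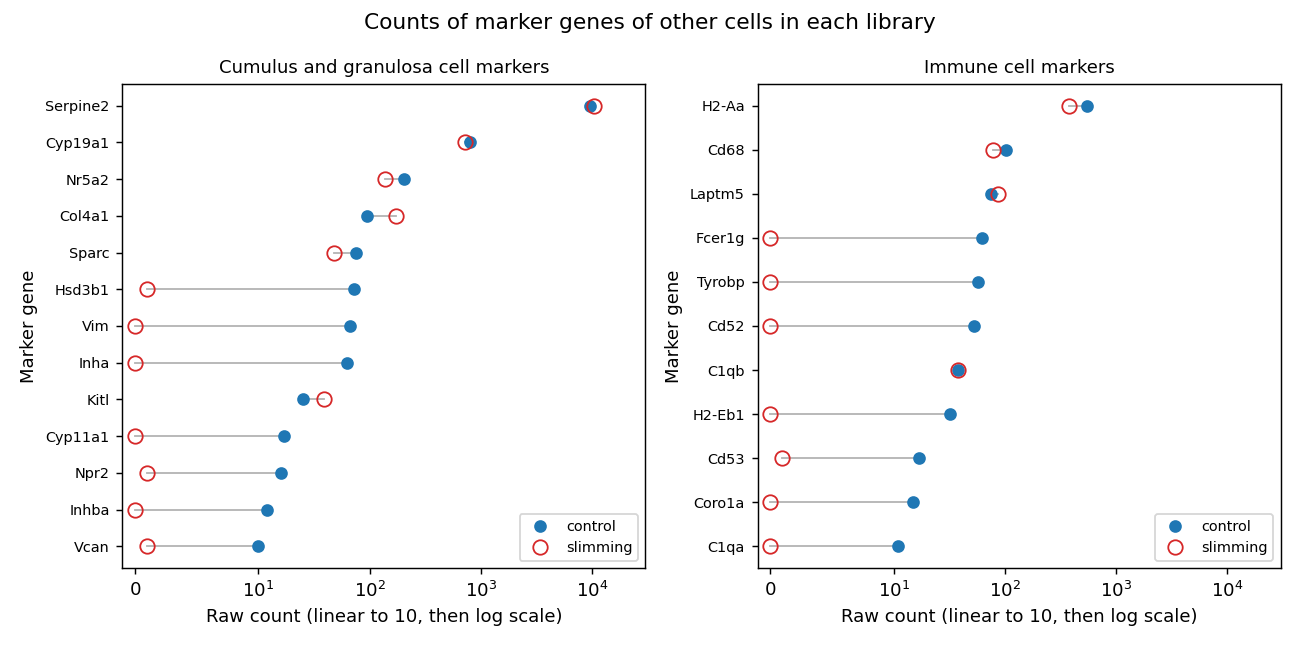
Raw counts of cumulus and granulosa markers (left) and immune markers (right) with at least 10 counts over both libraries, on an axis that is linear to 10 and logarithmic above; filled blue circles are the control and open red circles the slimming library. Markers such as Inha, Vim, Fcer1g and Tyrobp have 0 counts in the slimming library, while Serpine2 and Cyp19a1 lie close together.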

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

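The length-matched and GC-matched random lists and the removal of length and GC trends were chosen after the data were seen. Scaling by total count or DESeq2 size factors, and an added value of 5, left the counts of 2-fold genes within 1.5 times and moved the median of the expressed genes by at most 0.03. The scalings cannot move a list's shift, which is taken relative to that median, and say nothing about the lists; with the added value of 5 the 25 lists lay on the same side of the limits. Genes at least 2-fold higher and lower numbered 1038 and 987 with a minimum of 1 CPM, 24 and 15 with 50 CPM, and 3186 and 3774 with no minimum, since more or fewer low genes enter. At 4-fold they numbered 14 and 10, at 1.5-fold 590 and 409, and with the interval wholly beyond 2-fold 78 and 57. Pearson's r was 0.982 with no minimum, and Spearman's rho was 0.954 with a minimum of 1, 0.946 with 50 and 0.922 with none. Lists outside the limits numbered 3 with no minimum and 3 with the mean of the members.

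The oxidative phosphorylation list stayed between percentiles 99.84 and 100 and oxidative stress defence between 98.6 and 100 with other minima, the mean, coarser matching, matching on length or GC content, and trends removed. The tricarboxylic acid cycle moved to 3.56 with no minimum and 8.44 with the mean. The insulin list moved to 11.3 with a minimum of 50 and 3.87 against length-matched lists. The AMPK list moved to 18.3 with a minimum of 1, 6.49 with none, 11.1 with the mean and 5.70 with trends removed. Imprinted genes moved to 12.4 with a minimum of 1, 8.08 with 50, 2.81 with none, 21.6 with the mean and 6.63 with trends removed. In the other direction, glycolysis moved outside the limits to 1.58 with a minimum of 1, DNA repair to 1.45 and translation factors to 0.32 with 50, translation factors to 0.615 with the minimum in the mean, and ribosomal proteins to 0.79 against length-matched lists and 0.15 with trends removed. The cause was not tested. A minimum of 50 left 4 lists with too few members for a value. Choosing 1 feature per symbol was not run, since no symbol had more than 1. No paired analysis was possible because each group was 1 library, which also rules out leaving a library out. Between 1 and 10 CPM 26.1% of genes were at least 2-fold apart, where read counting alone gives 0.515%; with single pools and PCR copies not told apart, what limits low genes was not tested.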

Other observations

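The list of mRNAs encoded by the mitochondrial genome, the split of the respiratory chain by complex, the counts of genes found in 1 library and the counting test on immune markers were chosen only after results had been seen, as were the genes named in this part.

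The mRNAs of the mitochondrial genome lay on the opposite side from the median of the nuclear-encoded oxidative phosphorylation list, which holds no complex II genes. Each of the 7 expressed protein-coding genes of the mitochondrial chromosome was lower in the slimming library than the median of the expressed genes, led by mt-Nd4 (log2 -0.44), mt-Co1 (-0.40) and mt-Nd1 (-0.37), while mt-Nd6 was nearest to equal at -0.12. Their median shift was -0.30 (95% interval -0.46 to -0.14), at percentile 2.29 of random lists, just under the limit of 2.5. Those random lists were matched on expression and not on length or GC content. Both the interval and the percentile treat the 7 as separate values, although mRNAs of the same genome can vary together. The 13 protein-coding genes of that chromosome together held 4283 CPM against 5213 CPM. Those not called expressed had few counts, such as mt-Co3 (48 slimming against 71 control) and mt-Co2 (26 in each). With the treatment of reads with several matches not given, it was not tested whether such counts reflect the mRNA level. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 had log2 ratios of -0.37 and -0.33. Among the nuclear genes, 18 of 22 complex I members lay above the median of the expressed genes with a median shift of 0.57, and 6 of 7 members of complex IV with 0.48. The 8 expressed ATP synthase members were more mixed, with 5 above and 3 below and a median shift of 0.17, and 3 of 5 members of complex III lay above (0.40).

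Genes seen in 1 library were unevenly shared. With at least 30 counts in the other library, 44 genes had 0 counts in the slimming and 17 had 0 counts in the control library. The first group held Lgals1 (176 control counts, 62.0-fold lower against the floor of 3 counts), the cytokine Il1b (107 counts), the chemokine Ccl9 (95), the muscle acetylcholine receptor subunit Chrnd (93), the chemokine Ccl6 (88), Cd83 (70), the intermediate filament gene Vim (66), and Fsd2 and the inhibin subunit Inha (63 each). The steroid enzyme gene Hsd3b1 had 1 count against 72. The second group was led by Kcnn3 (58 slimming counts), Rbbp9 (56) and Tmod4 (54) and also held the smooth muscle actin Acta2 (43) and Trac (42), the constant part of the T cell receptor alpha chain, an immune transcript on the opposite side.

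The first pattern weighed is the higher nuclear-encoded oxidative phosphorylation list. Transcript length was related to the log2 ratio across genes (Spearman's rho -0.22), but against random lists matched on length the list lay at percentile 99.92, and removing the length trend took its shift from 0.45 to 0.22 with an interval (0.0039 to 0.41) just above 0. With length and GC trends removed together the shift was 0.20, for which no interval was computed. Length may thus account for part of the shift. The length-matched percentile goes against length as the whole source only as far as 10 bins of length can match it. Members may be shorter than their matches within a bin, and they can vary together. A bound this close to 0 cannot settle the question either. Matching on GC content left the list at percentile 100, with a GC-adjusted shift of 0.41 (0.18 to 0.60), which argues against GC content. The slimming regime, other differences between the mothers and differences between 2 single amplifications stay open and were not tested.

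The second is the higher oxidative stress defence list. Matching on GC content left it at percentile 99.98 with an adjusted shift of 0.37 (0.07 to 0.55), which argues against GC content as the whole source. Against length-matched lists it lay at percentile 99.445, yet the length-adjusted shift of 0.25 had an interval from -0.08 to 0.54, so transcript length and a difference in these genes cannot be told apart with 19 members. The slimming regime stays open and untested here too.

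The third is the set of immune transcripts in the control library. Counting noise would split the immune marker counts about evenly, and the slimming share of 35.7% (33.4 to 38.1) argues against noise of read counting alone, though not against chance in the capture and PCR of few molecules. RNA of immune cells in the control tube is a candidate source: 12 immune markers were seen in the control library alone and 0 in the slimming library alone, and 11 against 1 of a separate list of macrophage genes, but so were 8 against 1 of the cumulus and granulosa markers, and 2186 against 1551 of the genes with counts. The macrophage list, written before its values were seen, was meant for genes that oocytes carry at low level. It was predicted to have a median log2 ratio under -0.5 and had -0.10 (-0.58 to 0.32) over 26 genes. Yet 10 of these were expressed in the oocyte libraries, led by Grn (1222 CPM in slimming, 925 in control). For those genes the premise failed, so the median cannot decide on RNA of immune cells. Members of the list went both ways, with Cxcl2 at 0 slimming against 32 control counts, Tnf at 0 against 24 and Apoe at 202 against 425. Ccl2, by contrast, had 32 against 1. The source therefore stays open between immune cells, other somatic cells (how cumulus cells were removed is not given in the sources used here) and uneven capture of rare transcripts from 9 oocytes, which was not tested.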
